A study of Mus musculus with 4 samples.

How the data were processed

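Zac1 (also known as Plagl1) is a zinc finger transcription factor encoded by an imprinted gene. The series mapped its binding in Neuro-2A, a mouse neuroblastoma cell line, after transfection with a Zac1 expression plasmid. Per the labels' protocols, chromatin was fixed 16 hours after transfection, sonicated and precipitated with an in-house antibody against Zac1. Libraries were made from 10 ng of DNA, size-selected at 200 bp with adapters and amplified by 18 cycles of PCR. The labels give 4 libraries in 2 groups, with 2 immunoprecipitated (ChIP) libraries and 2 input libraries numbered as replicates 1 and 2. No cells without Zac1 plasmid and no precipitation with a control antibody were analysed here, so input chromatin is the only background.

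The series is analysed from a single peak table. Its column names are those of the peak caller CisGenome, per the file headers, and the submitters' processing notes name the genome build mm9. The aligner, the read filters, the detection thresholds and the way the replicates were combined are not given in the sources used here. The table holds 1 ChIP value and 1 input value per peak, so spread between replicates was not measurable and values carry no SD. Whether both libraries of a group entered each value is not stated.

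Per the file headers, the table gives the authors' whole-number read counts per peak region for the ChIP and for the input, and the same counts split by strand. The counts of the strands summed to the total in 4638 of 4638 peaks. Per the file headers, the deposited fold value is the largest window ratio of ChIP to input, and the values showed it to be on a log2 scale with a pseudocount of 1. In 100.0% of peaks it could be matched, within rounding, by whole-number ChIP and input counts no larger than those of the busiest window. Input counts were multiplied by a constant of 0.6961 for this. Without scaling, 84.1% could be matched. A window without input reads matches any constant, so only part of the peaks inform it. This constant was therefore taken as the authors' scaling of input to ChIP and used for every fold computed here. The false discovery rate in the deposited table is a p-value-like quantity from the authors' peak caller, written to 6 decimals. The deposited strand balance is the fraction of the weaker to the stronger strand's linear fold. The authors' rank is a score that orders peaks, and it was used only to describe and filter peaks of this list. Ranks run to 4688, and 50 ranks, rank 1 included, were not analysed here.

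Folds over scaled input were computed from the region counts with exact (Clopper-Pearson) 95% intervals of the conditional binomial. The regions were selected for enrichment on these reads, so no test of enrichment was made. PCR duplicates cannot be told from independent molecules in such counts, and the intervals cover counting error only. Library totals are not given in the sources used here, so depth is stated as reads within peaks: 388156 for ChIP and 20321 for input.

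Positions are given on mm9 as in the deposited table. The only gene table used here belongs to another assembly (GRCm38.p6), and positions were not converted. Peaks were therefore not assigned to genes, and 12 gene lists fixed before the data were examined (imprinted, extracellular matrix, earlier reported targets and others), the promoter comparisons and a motif search were not tested. The gene table served only to count the 49943 named genes per chromosome. Peaks per chromosome were tested against that share with a two-sided exact binomial test and Benjamini-Hochberg adjustment over 21 chromosomes, with significance at an adjusted p under 0.05. Peaks are not replicates, and these p-values describe the list, not its repeatability. On simulated sets of 4638 peaks, the test recovered 100.0% of chromosomes changed to a fold of 0.5 and 100.0% of those changed to a fold of 2. It made at least 1 call in 7.0% of 100 sets without any change. The simulated peaks were drawn independently, whereas the listed peaks cluster, so this rate does not carry over to them.

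Clustering along chromosomes was measured as the share of peaks with another peak within 10 kb, between midpoints. It was compared with 10000 random placements of every peak within its own 10 Mb window (a permutation test). Its p-value is the smaller of both tails, without doubling. The random positions ignore gaps and repeats of the assembly. This test replaced the planned one, which needed genes. The rule fixed beforehand named the 10 best ranked peaks, and its parts based on genes could not be applied. Other regions named here were chosen after their values were seen, as were the strand minimum of 28 reads (the highest of those examined), the 4 chromosomes with most peaks, the 10 densest windows, the limits of 120 and 70 Mb and the joining distances. The alternatives were stricter rank and read thresholds, other gene backgrounds, merging of neighbouring peaks, other distances and the omission of chromosomes. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.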

Results

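To determine where Zac1 binds in Neuro-2A neuroblastoma cells that overexpress it, chromatin precipitated with an anti-Zac1 antibody was compared with input chromatin. The series has 2 libraries of each, and whether both entered the values is not stated. The peak table analysed here holds 4638 peaks on 20 chromosomes, with 388156 ChIP reads and 20321 input reads inside them. Each peak carries 1 ChIP and 1 input value, so the comparison has no replicate check.

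The listed Zac1 peaks were short, strongly enriched and balanced between strands. The median peak held 75 ChIP reads (interquartile range 60 to 97) and 4 input reads (2 to 6). Over all peaks, ChIP reads exceeded scaled input reads 27.4-fold (95% exact interval 27.1 to 27.8, counting error only). Among the 4396 peaks with at least 1 input read the fold ranged from 5.22 to 250.0, with a median of 29.0, and 242 peaks had no input read. The lower limit of the fold was above 1 in 4638 of 4638 peaks and above 5 in 4528. These regions were selected for enrichment on the same reads, so the folds describe the list. In the authors' deposited table the largest window fold had a median log2 value of 4.95, from 2.42 to 6.36, and the false discovery rate was 0 to 6 decimals in 4631 peaks and at most 0.000239 in the other 7.

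The forward strand carried 50.1% of ChIP reads and 50.3% of input reads in the peaks. The summit of reverse reads lay a median of 68 bp (interquartile range 33 to 103) beyond the summit of forward reads, and this distance equalled the deposited peak length in 77.4% of peaks. The deposited length thus mostly reflects the spacing of the strand summits and does not measure the width of binding. The median length was 83 bp, and 714 peaks (15.4%) spanned 200 bp or more. In 569 peaks (12.3%) the order of the summits was inverted or the distance was 0. Those peaks had a median length of 391 bp against 76 bp for the remainder, and a median of 87 against 73 ChIP reads, while the median log2 fold in the authors' deposited table was 4.95 in both sets.

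No peak had fewer than 16 ChIP reads in the busiest window of its weaker strand, and 1023 peaks (22.1%) sat exactly at 16. Every listed peak thus had reads on both strands, so strand balance also describes the list. A total of 52.7% had 18 or fewer. Sites with less read support were not analysed here.

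**Figure D1:**
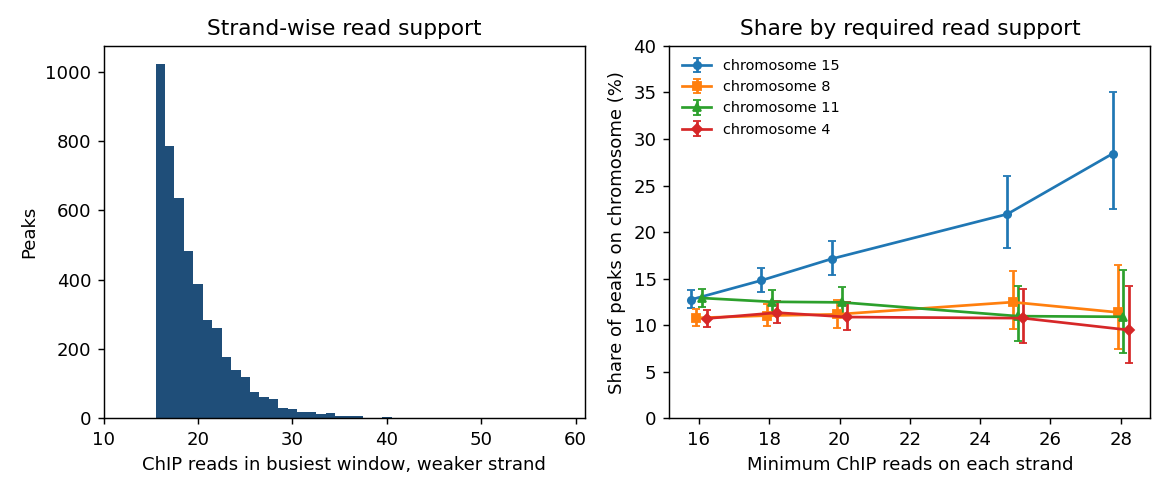
Left, number of peaks by ChIP reads in the busiest window of the weaker strand; the distribution starts at its highest bar, at 16 reads. Right, share of peaks (%, with 95% exact binomial intervals) on chromosomes 15, 8, 11 and 4 as the minimum number of ChIP reads on each strand is raised; the share of chromosome 15 goes from 12.7% at 16 reads to 28.4% at 28.

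Chromosome 15 held 6 of the 10 best ranked peaks in the table and 28 of the 100 best. The peak with the best rank in the table was on chromosome 1 (90131719 to 90131768), with 194 ChIP and 7 input reads, a 39.8-fold excess (95% interval 18.96 to 100.3). The next was on chromosome 13 (97985018 to 97985084), with 134 and 2 reads. On chromosome 15, a 695 bp peak at 78985907 to 78986601 had 282 ChIP and 3 input reads (135.0-fold, 45.7 to 658.7), and a 556 bp peak at 82997449 to 82998004 had 241 and 16 (21.6-fold, 13.1 to 38.5). The peak at 102841829 to 102841891 had 140 and 5 reads, and the peak at 76078385 to 76078517 had 205 and 12. At 99257812 to 99257844, 382 ChIP reads faced 11 input reads (49.9-fold, 27.6 to 100.8), the largest ChIP count among these 10, and at 97631634 to 97631666 the counts were 211 and 9. The other two were on chromosome 2 (30728241 to 30728311, 152 ChIP reads and 1 input read) and chromosome 8 (26180842 to 26180901, 200 and 14).

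Peaks were very unevenly shared between chromosomes. Chromosomes 11, 15, 8 and 4 held 599, 591, 500 and 497 peaks, together 47.2% of the list against 20.4% of named genes. Relative to its number of genes, chromosome 15 had 3.59 times the expected peaks (95% interval 3.32 to 3.87), chromosome 8 had 2.26 times (2.08 to 2.46), chromosome 11 had 2.09 times (1.94 to 2.25) and chromosome 4 had 1.83 times (1.68 to 1.99). Chromosomes 2, 10 and 5 exceeded expectation by less, at 1.19, 1.19 and 1.16 times. At the other end, the X chromosome held 3 peaks where 233.3 were expected (0.0129 times, 0.00265 to 0.0376) and chromosome 14 held 19 against 216.2 (0.0879 times, 0.0530 to 0.137). Chromosome 18 held 0.301, chromosome 9 0.403, chromosome 3 0.411, chromosome 19 0.415 and chromosome 12 0.481 times the expected number. Chromosome Y held 0 peaks where 36.1 were expected (exact 95% upper limit 0.102 times). By the exact binomial test with Benjamini-Hochberg adjustment, 7 of 21 chromosomes were above expectation, 13 were below and chromosome 6 (266 peaks, adjusted p = 0.975) did not differ. The excess of chromosomes 2, 5 and 10 no longer passed the test among the 1000 best ranked peaks, nor did the deficit of chromosome 13 with at least 20 reads per strand. After peaks within 10 kb were merged, the deficits of chromosomes 1 and 13 did not pass either (exact binomial test, adjusted p = 0.0939 and 0.0536).

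**Figure D2:**
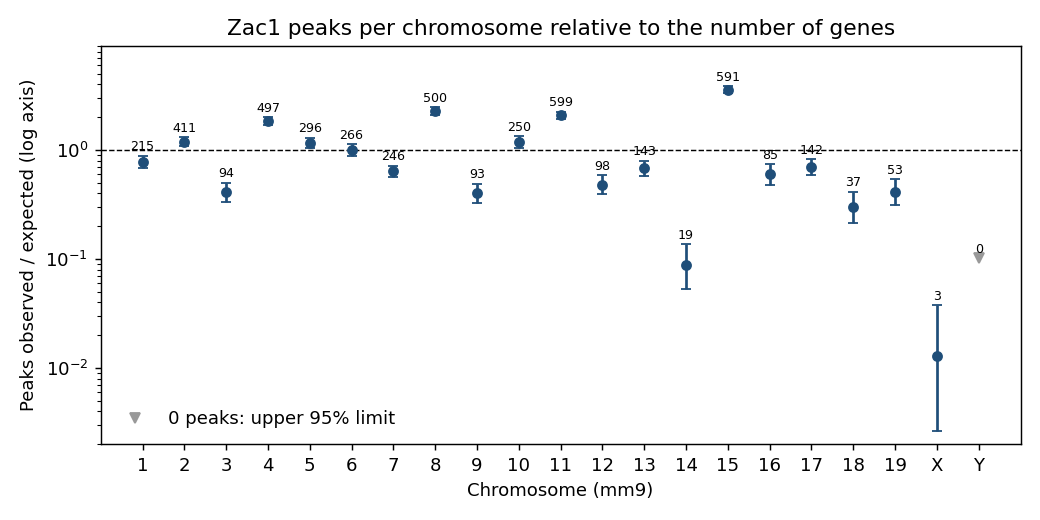
Observed over expected number of Zac1 peaks per chromosome, on a log axis, with 95% exact binomial intervals and the number of peaks above each point; the dashed line marks the share expected from the number of genes. Chromosome 15 is highest at 3.59 and X lowest of those with peaks at 0.0129, and Y, with 0 peaks, is drawn at its upper limit.

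Of the 3 X-linked peaks, 2 lay side by side, at 137372955 to 137373667 (160 ChIP and 2 input reads) and at 137374424 to 137374522 (70 and 0). The third, at 84483713 to 84483755, had 38 ChIP reads and 5 input reads.

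Peaks on chromosome 15 also held more ChIP reads. Their median was 84 ChIP reads per peak against 60 to 79 on the other chromosomes with peaks. At least 28 reads in the busiest window of each strand were reached by 10.2% of peaks on chromosome 15 and by 3.73% elsewhere at a limit chosen after the data were seen (odds ratio 2.92, Fisher's exact test, two-sided, adjusted p = 1.85e-09 over 4 chromosomes). For chromosomes 8, 11 and 4 the same comparison gave odds ratios of 1.07, 0.818 and 0.867, each with an adjusted p of 0.734 by Fisher's exact test. Peaks are not replicates and cluster along chromosomes, so these p-values describe the list only. In the authors' deposited table, the median log2 fold was 5.00 on chromosome 15, as on chromosomes 5, 7, 11, 12, 17 and 19, and lay between 4.75 and 5.04 over the chromosomes with peaks. Because windows without input reads give a fold set by ChIP reads alone, this narrow range does not show equal enrichment. Input reads per peak differed too, without following peak number throughout. They were highest on chromosome 18 (5.89), which held few peaks. That value rests mostly on 30 of its 37 peaks, between 30 and 40 Mb, with 6.67 input reads per peak. Its 5 peaks between 60 and 70 Mb had 2.2. Next came chromosomes 15 (5.51), 8 (5.05), 13 (5.04), 12 (4.69), 4 (4.66), 6 (4.32) and 11 (4.19). The lowest were chromosome 14 (2.42) and X (2.33).

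Within chromosomes, binding was concentrated in a few stretches. Of 268 windows of 10 Mb up to the last peak of each chromosome, 64 held no peak, and 21 windows held at least 50% of all peaks. The 10 densest windows held 1552 peaks (33.5%). The window from 130 to 140 Mb of chromosome 4 had 240 peaks, that from 120 to 130 Mb of chromosome 8 had 237, and that from 70 to 80 Mb of chromosome 15 had 221. On chromosome 4, 485 of 497 peaks (97.6%) lay beyond 120 Mb, and on chromosome 15, 557 of 591 (94.2%) lay beyond 70 Mb.

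**Figure D3:**
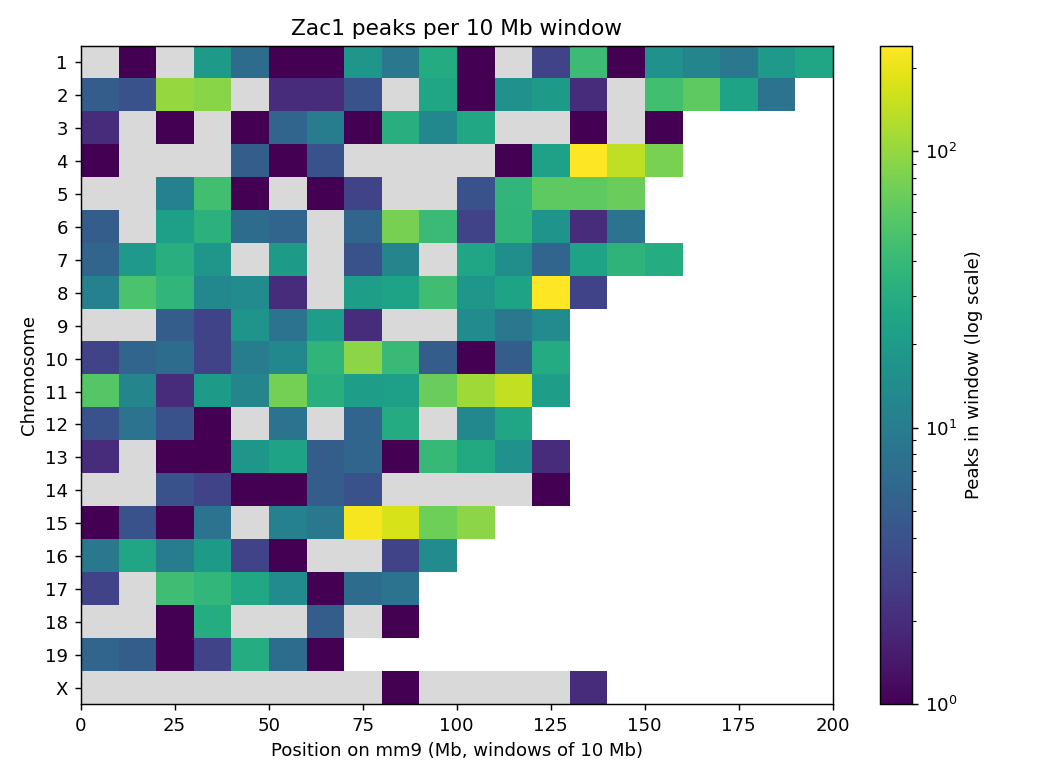
Number of Zac1 peaks per 10 Mb window along each mm9 chromosome (colour, log scale; grey, no peak; white, beyond the window of the last peak). The brightest windows are on chromosomes 4 (130 to 140 Mb, 240 peaks), 8 (120 to 130 Mb, 237 peaks) and 15 (70 to 80 Mb, 221 peaks).

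At short range, 1907 peaks (41.1%) had another peak within 10 kb. Random placement within the same 10 Mb windows gave 14.2% on average (95% of placements between 12.96% and 15.46%), a 2.89-fold difference, with p = 0.0001 in the permutation test, the smallest that 10000 placements can give. The difference depended on the comparison: it was 1.65-fold when positions were drawn within 1 Mb windows (24.9%), 5.41-fold for neighbours within 1 kb and 1.33-fold for neighbours within 100 kb. When peaks at most 10 kb apart were joined end to end, 700 groups of 2 or more peaks took in 1921 peaks, and 4 groups had 10 or more. The largest, of 17 peaks over 61.4 kb, was on chromosome 4 (140554955 to 140616330), with 1797 ChIP and 117 input reads (22.1-fold, 18.3 to 26.8). A group of 13 peaks was on chromosome 5 (125614829 to 125657899, 16.9-fold, 13.7 to 21.0). Groups of 10 were on chromosome 15 (82973590 to 83004561, 22.5-fold, 18.0 to 28.5) and near the distal end of the list on chromosome 7 (149711593 to 149758349, 30.4-fold, 23.0 to 41.0). Joined at 100 kb, the largest domains were 99 peaks over 1393 kb on chromosome 4 (139586656 to 140980061), 90 peaks over 1069 kb on chromosome 15 (78259803 to 79328673) and 72 peaks over 844 kb on chromosome 8 (122314451 to 123158711).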

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

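Merging within 1 kb left 4388 of 4638 peaks, and a false discovery rate limit of 0.01 removed none, so it tests nothing. The number of chromosomes off expectation, 20 as reported, was between 16 and 20 under the 9 other alternatives, of which the rank thresholds were planned and the rest were chosen after seeing the data. Of 187 values per chromosome under these alternatives, 169 kept direction and call, 12 lost significance in the same direction (chromosomes 1, 2, 5, 10 and 13) and 6 reversed, all on chromosome 6, which was not called: 0.93 times expectation among the 2319 best ranked peaks, 0.91 among the 1000 best ranked, 0.93 without olfactory, vomeronasal and predicted genes, 0.998 after merging within 1 kb, 0.95 with at least 20 reads per strand and 0.99 without chromosome Y. The cause was not tested. The enrichment of 27.4-fold over all peaks was 19.1 without scaling of the input and 21.2 from the busiest windows. It was 36.0 among the 2319 best ranked peaks and 38.9 among the 1000 best. Among the 10 best ranked peaks the rank followed the deposited fold, so a higher fold in better ranked peaks comes largely from the ranking. The excess of near neighbours, 2.89-fold, lay between 1.33 and 5.41 under 6 alternatives, each with p = 0.0001 by permutation. No paired analysis was possible because the table holds 1 ChIP and 1 input value per peak, and for the same reason no replicate could be left out and replicate agreement was not run. The alternatives fixed beforehand for gene lists and promoter position were not run, and no motif search was made. The reason is that no genome of the same build was used here. The list starts at 16 reads per strand, and whether depth or a threshold of the peak caller sets this limit was not tested.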

Other observations

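The tests in this part, except that of peaks against gene number, were chosen after the results they bear on had been seen, and the measure of DNA amount was chosen after 2 forms of it had been tried. The site with the most ChIP reads, 409 against 28 input reads (21.0-fold, 14.3 to 32.0), was on chromosome 12 (110656103 to 110656205). Its authors' rank was 335, and its deposited log2 fold was 5.52 against 6.36 for the best ranked peak. On chromosome 18, 30 of 37 peaks lay between 30 and 40 Mb. The site with the most input reads, 57, was on chromosome 8 (125955660 to 125955838) and had 207 ChIP reads, a 5.22-fold excess (3.87 to 7.12) that was the lowest fold among peaks with input reads.

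The first pattern is the uneven number of peaks between chromosomes. Gene number was not sufficient, since chromosome 15 stood at 3.59 times its share of genes, nor was the listing of 1 region as several peaks within 10 kb, since 2.92 times remained after peaks within 10 kb were merged. A candidate explanation is the amount of DNA of each chromosome in the cells, because a site with more copies passes a fixed minimum of 16 reads per strand more easily. Input reads per peak, relative to the other chromosomes, were taken as the measure of DNA. The strand read distribution gave the peak number each ratio predicts. For chromosome 14, the observed 0.0834 times the peaks per gene of the other chromosomes lay within the predicted 0.00216 to 0.225. That range rests on 46 input reads and is so wide that lying within it says little. For chromosome 8, the observed 2.39 lay within the predicted 2.07 to 2.62. The prediction fell short for chromosome 15 (observed 3.93, predicted 2.49 to 3.14), chromosome 4 (1.91, predicted 1.25 to 1.55) and chromosome 11 (2.23, predicted 0.613 to 0.781). Each ratio was taken against all other peaks pooled, so chromosomes with many peaks weigh most in it, while the observed number is per gene. For chromosome 11 (4.19 input reads per peak), the pool includes chromosomes 15 (5.51), 8 (5.05) and 4 (4.66), which lowers its ratio of 0.951. A single ratio per chromosome, with every listed peak counted separately, thus did not give the peak number there. It cannot decide on DNA amount, because input reads per peak varied within chromosomes. On chromosome 4 they were 2.48 at 120 to 130 Mb and 5.31 at 140 to 150 Mb. On chromosome 11 they were 2.05 at 70 to 80 Mb and 5.41 at 100 to 110 Mb. Windows from 70 to 110 Mb of chromosome 15 differed less (5.06 to 5.89), but the pooled reference applies there too. After merging within 10 kb, chromosomes 15, 4 and 11 stood at 2.92, 1.55 and 2.07 times their share of genes. No prediction was made for merged peaks. DNA amount and split peaks together were therefore not tested. DNA amount, alone or with split peaks, stays open for chromosomes 15, 4 and 11. X (0.0121) stayed open because its peaks held only 7 input reads. Base composition and the true biology of the sites were not tested and remain open.

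The measure first tried for DNA amount was the input reads of a peak relative to the mean of peaks with similar ChIP reads, in 10 bins, and it was replaced by plain input reads per peak only after its result had been seen, on the argument that more DNA raises ChIP reads as well. With the first measure, the observed peak number again lay within the prediction for chromosomes 8 (1.60 to 2.62) and 14 (0.00606 to 0.286) and above it for chromosomes 15 (1.41 to 2.02), 4 (0.777 to 1.55) and 11 (0.613 to 1.30). Of 20 chromosomes, 10 lay within the prediction of the first measure, 7 above and 3 below, against 9, 8 and 3 with plain input reads. The 3 below were chromosomes 12, 13 and 18 with both. On chromosome 18, 30 of 37 peaks lay between 30 and 40 Mb, so its prediction mostly describes that stretch.

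In total, 12 correlations of these measures with the number of peaks were computed, and adjusted p-values are over all 12. For chromosomes this was the log2 of peaks per gene relative to the other chromosomes, and for windows the log2 peak number. Across the 20 chromosomes with peaks, the first measure had a Pearson r of 0.45 (permutation p = 0.0486, adjusted p = 0.110) and a Spearman rho of 0.44 (permutation p = 0.0548, adjusted p = 0.110), and r was 0.57 without chromosomes 18 and 14, the 2 farthest from the median of the measure. Plain input reads had an r of 0.62 (permutation p = 0.00280, adjusted p = 0.0168) and a rho of 0.53 (permutation p = 0.0189, adjusted p = 0.0566), and r was 0.74 without its 2 farthest, chromosomes 18 and 15. Of these 4 correlations over all 20 chromosomes, 1 passed after adjustment, and it belongs to the measure adopted later. Among the 18 chromosomes with 20 or more peaks, r was 0.16 (permutation p = 0.539, adjusted p = 0.539) and rho 0.25 (permutation p = 0.311, adjusted p = 0.373) for the first measure, and r was 0.35 (permutation p = 0.156, adjusted p = 0.208) and rho 0.35 (permutation p = 0.156, adjusted p = 0.208) for plain input reads, so neither measure passed the test without chromosome 14 and X. Leaving out the 2 farthest of these 18 as well gave an r of 0.53 for the first measure and 0.52 for plain input reads. Within chromosomes, over 138 windows of 10 Mb with 5 or more peaks, r was 0.065 (permutation p = 0.443, adjusted p = 0.483) and rho 0.15 (permutation p = 0.0837, adjusted p = 0.143) for the first measure, and r was 0.23 (permutation p = 0.00733, adjusted p = 0.0293) and rho 0.28 (permutation p = 0.000910, adjusted p = 0.0109) for plain input reads. Chromosomes and windows are not independent replicates.

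The second pattern is the concentration of peaks within chromosomes. The 10 densest windows held 155.2 peaks per 10 Mb against 17.1 in the other 76 windows of the same chromosomes, and their input reads per peak were 1.23 times higher (1.19 to 1.28). Because windows picked for density favour a high ratio, the picking was repeated in 100 random splits. In each, windows were picked on a part of the peaks and measured on the other part. With the strand minimum in the dense windows raised by the upper limit of the input ratio, a median 3.09-fold density remained (1.68 to 5.26 over splits). This argues against more DNA by that ratio, as far as input reads measure it, as the whole cause. A larger DNA difference stays open, because the ratio pools peaks while density counts windows. Among the other windows, input reads per peak were 2.48 at 120 to 130 Mb of chromosome 4 but 5.89 at 90 to 100 Mb of chromosome 15. Neighbours within 10 kb were 1.65 times as frequent as at random positions within 1 Mb windows, which leaves a gain of longer segments open, since a gain keeps whatever spacing its sites already have. Splitting of 1 region into peaks within 1 kb was not enough for the near neighbours, since 2.69 times the random frequency remained after merging at that distance, and splitting over longer distances, promoters and gene density were not tested.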
